A study of Mus musculus with 12 samples.

How the data were processed

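RNA of 12 mouse (C57BL/6) brain cell libraries was sequenced in 4 groups of 3, with 3 µg of RNA per sample and a library kit that does not mark strand, per the labels' protocols. Groups and replicate numbers were taken from the sample titles. The deposited file is 1 table of FPKM values per gene and library, which the authors normalized before they deposited it. It holds 55862 entries, of which 55421 carry a gene name. The submitters' processing notes name Bowtie 0.12.2 and the builds mm8 and mm9. The table's own coordinates are those of GRCm38, since of 55240 gene identifiers shared with GENCODE M21, 54985 (99.5%) have the same coordinates and strand. The tool that counted reads is not given in the sources used here. The 441 entries without a gene name held 0.0957% to 0.156% of reads and stayed out of the tests.

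Each FPKM value of the deposited table multiplied by the gene's length gave whole reads, within 0.01, for 100% of values in every library. The recovered reads per library numbered 17077780 to 24452419. The library totals that the FPKM values imply differ from these sums by factors of 0.744 to 1.2183, so the authors' values include a scaling between libraries, by a method that the sources used here do not give. At these depths 1 read in a gene of 1 kb is worth 0.0343 to 0.0623 FPKM, which limits the precision of low values, and this covers counting error only. No pair of replicate libraries differed by as little as counting noise (chi-square per degree of freedom 2.63 to 105), so no library was counted as a duplicate.

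Values were analysed as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (with the package data.table, version 1.17.8), with an empirical Bayes estimate of the spread that follows the mean. Because the pseudocount is 1, fold changes of genes with low values are understated. Genes at 1 FPKM or more in at least 3 libraries were tested, 15747 in all. All 12 libraries entered 1 fit with a mean per group and no covariate, and 6 comparisons were drawn from it. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 over the genes of a comparison, and counts at 2-fold or more were made as well. Tables and figures were made in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

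The groups, the tests, the gene lists, the rule for named genes and a set of other settings to try were fixed before the data were examined. The 35 lists were markers of neural stem and progenitor cells, astrocytes, reactive astrocytes, neurons, the oligodendrocyte lineage, microglia and macrophages, endothelium, fibroblasts and mural cells, and ependyma and cilia. They also covered genes of mitosis, DNA replication, pluripotency, the hypoxia response, glycolysis, oxidative phosphorylation, the extracellular matrix, integrins and cadherins, YAP and TEAD targets, and the actin cytoskeleton with SRF targets. The others held genes of the Notch, Wnt, Hedgehog and BMP pathways, interferon-stimulated genes, inflammatory and NF-kB targets, p53 targets and senescence, and the ER stress and amino acid response. The rest were cholesterol synthesis, immediate early genes, mesenchymal transition transcription factors, forebrain patterning, hindbrain and Hox genes, chromatin modifiers, red blood cell genes and sex-linked genes. Some lists share members: 5 of 22 stem and progenitor markers, 3 of 35 reactive astrocyte genes and 2 of 28 interferon-stimulated genes stand in another list, and 0 of the oligodendrocyte, microglia, endothelial, fibroblast and ependymal lists do. Lists with 5 or more measured members were tested with camera, part of limma, with a preset correlation of 0.01 between genes, adjusted over the lists of a comparison. A call was repeated with a correlation estimated per list, and with fry, also part of limma, as alternatives.

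The rule for named genes took, among called genes whose groups did not overlap and whose mean was at least 10 FPKM in the higher group, those with the largest changes: 8 higher and 8 lower in A-iSC against AST, 4 and 4 in each other comparison. Names of predicted genes, clones and pseudogenes were passed over. From each list it took the called members of largest change, at most 4 in A-iSC against AST and 3 in the others, and in every comparison Nes, Sox2, Pax6, Gfap, Aqp4, S100b, Mki67, Tubb3, Olig2 and Cd44. Fewer of these are given here, and some are not reported here. Genes outside the rule are marked as chosen after their values were seen.

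How far A-iSC changed in the same way as the NSC groups was measured on genes called at 2-fold or more in the same direction in both NSC groups against AST. The same shares and correlations were computed for 100 simulated draws of unchanged groups against the same AST libraries. Distances were 1 minus the Spearman correlation of log2 values, tested by exact permutation. The fit was tested on simulated data for A-iSC against AST (12873 genes, 200 of them changed). It recovered 37.3%, 79.1% and 98.5% of genes changed 1.5-fold, 2-fold and 4-fold. It called 7 of 12673 unchanged genes (4.67% of calls) and 0 of 100 random lists, which do not test lists whose genes vary together.

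These settings were pseudocounts of 0.1 and 5, no filter or 5 FPKM as the filter, quantile and median-ratio scaling, a robust spread estimate, a fit of the 2 groups alone, a block for the replicate number, each library left out in turn, lists without shared members, other limits of the shared NSC set (no fold limit or 4-fold) and other distances. Chosen after the data were seen were limma-voom on the recovered reads, scaling by total reads and 3 kinds of setting for a split within AST and A-iSC that follows gene length. The split was defined where the correlation of a library's deviation with gene length passed 0.2 on each side of 0 within a group, a limit set after the values were seen. P56-NSC, at -0.264 to 0.196, fell just short of it.

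Reads of near-identical genes cannot be assigned with certainty, which concerns the globins Hba-a1 and the other Hba and Hbb genes, Gapdh with its pseudogenes, C4b, Serpina3n, Ifit3 and Lyz2. Without strand, reads of antisense and overlapping genes are uncertain too. A gene listed at 0 in all libraries of a group is given without a fold change against that group.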

Results

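Gene expression was measured by RNA sequencing in 12 libraries of mouse (C57BL/6) brain cells that fell into 4 groups of 3. The AST group held astrocytes sampled at 0 days of incubation and served as the negative control of the design. The A-iSC group held cells obtained from such astrocytes after 5 days of incubation as 3D spheres. By their labels, the P56-NSC and P0-NSC groups held neural progenitor cells taken from the brain and served as positive controls. The labels do not state that the 3 libraries of a group came from separate cultures or animals, so the p-values measure only the spread between these libraries, which may be technical. Whole reads recovered from the deposited FPKM values numbered 17077780, 21543424 and 18862805 in AST and 18288177, 20717958 and 23769070 in A-iSC. They numbered 22285109, 21575734 and 21380187 in P56-NSC and 18778071, 24452419 and 24025278 in P0-NSC. At these depths 1 read in a gene of 1 kb was worth 0.0343 to 0.0623 FPKM. Levels are given as the mean FPKM ± SD of the 3 libraries of a group. Log2 changes are on the log2(FPKM + 1) scale, with their standard errors.

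The first principal component of log2(FPKM + 1) held 52.6% of the variance and placed A-iSC between AST and the NSC groups. The second held 27.9% and separated P0-NSC from the other groups. The third held 14.2% and set A-iSC (scores of -60.6 to -48.05) apart from all other libraries (-4.93 to 41.2).

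**Figure D1:**
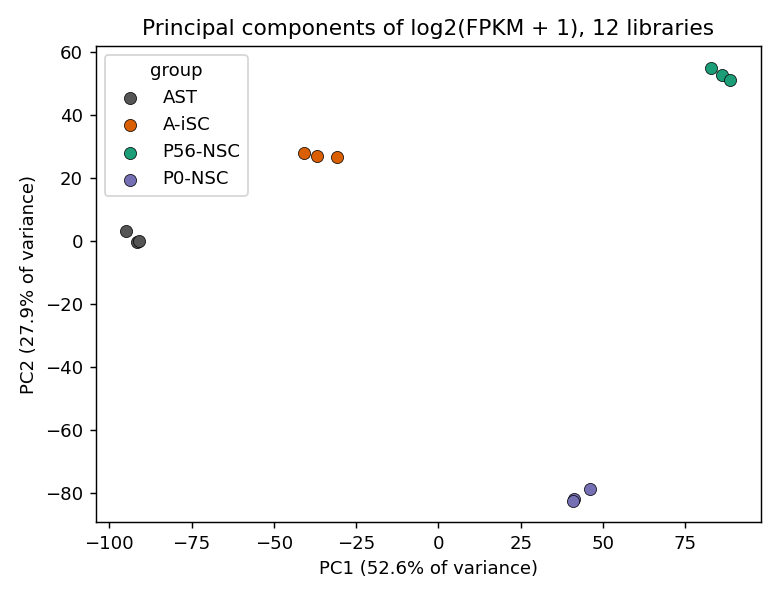
Principal components of log2(FPKM + 1) over the 15747 genes tested, with 1 point per library (3 libraries in each of 4 groups). The horizontal axis is the first component (52.6% of the variance) and the vertical axis the second (27.9%), both in units of the component score, and A-iSC lies between AST and the NSC groups on the first.

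The comparison of A-iSC with AST asked what changed in astrocytes over 5 days in spheres. Most astrocyte markers and all 20 microglia and macrophage markers rose (median log2 changes 1.69 and 3.15), while most genes of the contractile cytoskeleton, of the extracellular matrix and of cell division fell. The astrocyte, microglia, matrix and mitosis lists lost their calls with an estimated correlation (adjusted p = 0.174, 0.0852, 0.174 and 0.0852). Gfap, the intermediate filament protein of astrocytes (ENSMUSG00000020932, chromosome 11: 102887336 to 102900912, build GRCm38), rose from 29.9 ± 2.30 to 970.0 ± 448 FPKM (n = 3 per group; log2 change 4.88 ± 0.26, limma adjusted p = 1.97e-08). Apoe, a lipid carrier made by glia, rose from 589 ± 107 to 10899 ± 1787 FPKM (log2 change 4.21 ± 0.21, limma adjusted p = 1.14e-08). Acta2, the actin of smooth muscle (ENSMUSG00000035783, chromosome 19: 34241090 to 34255590), dropped from 1848 ± 231 to 41.6 ± 16.6 FPKM (log2 change -5.51 ± 0.39, limma adjusted p = 2.44e-07). Col1a1, a chain of collagen I, dropped from 158 ± 24.2 to 2.98 ± 0.576 FPKM. Of 15747 genes tested, 9279 were called (limma adjusted p below 0.05), 4429 of them higher and 4850 lower in A-iSC. A change of 2-fold or more was called for 2955 genes, 1441 higher and 1514 lower.

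Among genes with a mean of at least 10 FPKM in the higher group, the largest rise was that of Ripply1, a transcriptional repressor known from somite formation (ENSMUSG00000072945, chromosome X: 139779549 to 139782353). It went from 0.177 ± 0.0962 to 68.0 ± 18.6 FPKM (log2 change 5.84 ± 0.16, limma adjusted p = 4.17e-10). Next came the neurotensin receptor Ntsr2 (39.1 ± 11.8 FPKM in A-iSC), the complement gene C4b (45.2 ± 10.1) and the apolipoprotein Apoc1 (51.2 ± 11.9). They were followed by the angiotensinogen gene Agt (38.8 ± 9.42), Gfap, the aldolase Aldoc (406 ± 94.9) and the protease inhibitor Serpina3n (285 ± 107). The 8 largest falls were those of Tinagl1, the retinoic acid-binding protein Crabp1, the collagen cross-linking enzyme Lox, Crct1, Acta2, the matrix proteoglycan Fmod, Col1a1 and the matrix glycoprotein Thbs1. Tinagl1 dropped from 79.3 ± 3.24 to 0.295 ± 0.0415 FPKM (log2 change -5.95 ± 0.21, limma adjusted p = 1.08e-09) and Thbs1 from 723 ± 104 to 18.9 ± 3.81 FPKM.

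Of 22 astrocyte markers, 17 rose and 1 fell (camera adjusted p = 8.38e-08, and adjusted p = 0.174 with an estimated correlation). Aqp4, the water channel of astrocyte endfeet, rose from 30.8 ± 2.92 to 92.4 ± 38.5 FPKM (log2 change 1.48 ± 0.28, limma adjusted p = 0.000632), and S100b from 3.11 ± 0.469 to 11.4 ± 0.992 FPKM. Of 33 reactive astrocyte genes, 18 rose and 12 fell (camera adjusted p = 0.0657, and 0.0358 under quantile normalization). The complement gene C3 among them went from 0.580 ± 0.0497 to 17.9 ± 4.74 FPKM and the protease inhibitor Timp1 from 351 ± 62.5 to 41.7 ± 9.55 FPKM. Cd44, a hyaluronan receptor, fell by 1.71 ± 0.10 on the log2 scale, to 31.3 ± 3.14 FPKM. All 20 microglia and macrophage markers rose (camera adjusted p = 3.1e-12, and adjusted p = 0.0852 with an estimated correlation). The complement gene C1qa rose from 87.1 ± 14.1 to 1029 ± 192 FPKM and the protease gene Ctss from 75.2 ± 6.87 to 978 ± 70.2 FPKM. In these same libraries 21 of 28 interferon-stimulated genes rose and 0 fell (camera adjusted p = 1.46e-06, and adjusted p = 0.295 with an estimated correlation). Among them were the transcription factor Irf7 (7.02 ± 1.27 to 61.7 ± 19.9 FPKM) and the guanylate-binding protein Gbp2 (5.07 ± 0.243 to 34.2 ± 5.20 FPKM).

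Neural stem and progenitor markers went in both directions, with 9 of 22 higher and 5 lower (camera adjusted p = 0.176). The Notch effector Hes5 rose from 0.463 ± 0.199 to 7.88 ± 1.95 FPKM. Sox2, a transcription factor of neural progenitors, rose from 135 ± 20.2 to 208 ± 26.9 FPKM (log2 change 0.62 ± 0.14, limma adjusted p = 0.00186). Nes, the intermediate filament protein nestin, dropped from 196 ± 13.4 to 70.1 ± 5.01 FPKM (log2 change -1.47 ± 0.09, limma adjusted p = 5.38e-08). The Notch effector Hes1 fell by 2.26 ± 0.22 on the log2 scale, to 11.2 ± 4.25 FPKM. Pax6 was at 3.59 ± 0.129 in AST and 4.13 ± 0.533 FPKM in A-iSC (limma adjusted p = 0.168), a difference called in 3 of 26 alternatives (adjusted p = 0.0101 to 0.563).

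Of 22 neuronal markers 10 rose and 3 fell (camera adjusted p = 0.164). Dcx, a microtubule protein of migrating neurons, rose from 0.0833 ± 0.0245 to 2.86 ± 0.185 FPKM and the growth cone protein Stmn2 dropped from 53.8 ± 11.2 to 7.16 ± 1.65 FPKM. Tubb3, a neuronal tubulin, was at 40.7 ± 9.21 and 37.8 ± 9.68 FPKM (limma adjusted p = 0.658), called in 1 of 27 alternatives, the gene length covariate (adjusted p = 0.0319 to 0.837). Of 17 oligodendrocyte lineage markers 11 rose and 1 fell (camera adjusted p = 3.78e-05, and adjusted p = 0.174 with an estimated correlation). The lineage factor Sox10 went from 0.279 ± 0.174 to 11.2 ± 2.03 FPKM. Olig2 rose from 26.7 ± 0.915 to 35.9 ± 3.05 FPKM (log2 change 0.41 ± 0.13, limma adjusted p = 0.014), a call that ended in 3 of 27 alternatives, among them without A-iSC 1 (adjusted p = 0.0516, range 0.000574 to 0.183). Ependymal and cilia genes rose in 15 of 19 cases and fell in 0 (camera adjusted p = 1.79e-05, and adjusted p = 0.222 with an estimated correlation), among them the ciliary gene Tekt1 (0.208 ± 0.0577 to 7.77 ± 1.15 FPKM).

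All 27 mitosis genes fell (camera adjusted p = 3.74e-15, and adjusted p = 0.0852 with an estimated correlation), as did all 32 DNA replication genes (camera adjusted p = 8.75e-12). Rrm2, a subunit of ribonucleotide reductase, dropped from 126 ± 1.47 to 7.33 ± 0.399 FPKM (log2 change -3.93 ± 0.13, limma adjusted p = 8.48e-10). The mitotic kinase gene Plk1 dropped from 33.7 ± 3.85 to 3.59 ± 0.731 FPKM and the proliferation marker Mki67 from 15.1 ± 0.562 to 3.90 ± 0.205 FPKM. All 25 actin cytoskeleton and SRF target genes fell (camera adjusted p = 3.1e-12), as did 19 of 21 YAP and TEAD target genes with 0 higher (camera adjusted p = 2.7e-09). The YAP targets Ccn1 and Ccn2 dropped from 932 ± 35.7 to 92.3 ± 34.0 and from 319.8 ± 15.5 to 39.7 ± 11.8 FPKM. Of 38 extracellular matrix genes 31 fell and 5 rose (camera adjusted p = 7.29e-09), and of 21 integrins and cadherins 14 fell and 4 rose (camera adjusted p = 0.00447). Fibroblast and mural cell markers fell in 12 of 18 cases and rose in 2 (camera adjusted p = 0.000951). These 3 lists gave adjusted p = 0.174, 0.373 and 0.194 with an estimated correlation. Of 12 mesenchymal transition transcription factors 9 fell and 2 rose (camera adjusted p = 0.000957), with Twist1 dropping from 24.9 ± 4.64 to 1.70 ± 0.301 FPKM.

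Of 20 p53 target and senescence genes 17 fell and 1 rose (camera adjusted p = 1.46e-06), with the stress cytokine Gdf15 going from 93.6 ± 19.8 to 3.42 ± 1.85 FPKM. BMP target genes fell in 9 of 14 cases and rose in 1 (camera adjusted p = 0.00465, and adjusted p = 0.096 with an estimated correlation), with the inhibitory Smad6 going from 34.6 ± 0.448 to 6.33 ± 1.55 FPKM. Of 22 cholesterol synthesis genes 17 fell and 0 rose (camera adjusted p = 1.5e-05, and adjusted p = 0.119 with an estimated correlation). Of 39 oxidative phosphorylation genes 27 fell and 0 rose (camera adjusted p = 2.43e-05, and adjusted p = 0.373 with an estimated correlation), a call that ended under quantile normalization (adjusted p = 0.063). Reads from the mitochondrial genome made up 4.70% in AST 2, 7.03% in A-iSC 1 and 5.49% in A-iSC 2, and 2.94%, 3.17% and 3.05% in AST 1, AST 3 and A-iSC 3.

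No call was made by camera for 12 further lists. Notch pathway genes rose in 11 of 20 cases and fell in 2 (camera adjusted p = 0.0513, and 0.0333 without members shared with other lists), with the ligand gene Dll1 going from 1.07 ± 0.0650 to 4.66 ± 0.189 FPKM. Of 25 hypoxia response genes 11 rose and 7 fell (0.281), of 17 glycolysis genes 4 and 7 (0.635), of 15 Wnt target genes 2 and 6 (0.197, and 0.0479 under quantile normalization) and of 10 Hedgehog pathway genes 3 and 3 (0.929). Ccnd1, the G1 cyclin in the Wnt list, dropped from 428 ± 92.5 to 12.3 ± 2.13 FPKM. Inflammatory and NF-kB target genes rose in 8 and fell in 8 of 23 cases (0.864), ER stress and amino acid response genes in 6 and 11 of 23 (0.268) and immediate early genes in 2 and 9 of 17 (0.0977). Forebrain patterning genes rose in 7 and fell in 3 of 16 cases (0.265), chromatin modifiers in 8 and 10 of 21 (0.864) and endothelial markers in 1 and 5 of 13 (0.164, and 0.0245 under quantile normalization). The cytokine gene Csf1 dropped from 275 ± 2.11 to 20.6 ± 3.04 FPKM and the chromatin protein gene Hmga2 from 17.2 ± 1.43 to 0.859 ± 0.272 FPKM. Leaving out 1 library brought calls for the Notch list (without AST 1, AST 3, A-iSC 1, A-iSC 2 or any P56-NSC library, camera adjusted p = 0.0238 to 0.0498) and immediate early genes (without A-iSC 1, 0.0413). It did so for endothelial markers without any P0-NSC library (0.0338 to 0.0441) and for reactive astrocyte genes without AST 1 or AST 3 (0.0393 and 0.0407). Of 5 red blood cell genes 0 were called by limma, 0 at an unadjusted p under 0.05 and 0 by voom (camera adjusted p = 0.881).

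Lists with under 5 measured members were not tested as lists. Of these, 3 of 3 pluripotency genes fell (Klf4, Klf2 and Myc, all also active outside pluripotent cells), 1 of 4 hindbrain and Hox genes rose and 3 fell, and 1 of 4 sex-linked genes rose (Kdm5d, limma adjusted p = 0.00938, a call that ended in 2 of 26 alternatives, 4.11e-05 to 0.0841). The fall of Myc (limma adjusted p = 0.0332) ended in 11 of 27 alternatives (adjusted p = 0.00719 to 0.341), for example without AST 1, AST 2, AST 3 or A-iSC 3 (0.0503, 0.0809, 0.0791 and 0.109). Adjusted over the list alone, the counts were 19 up for the reactive list, 3 up for the fibroblast and mural list, 28 down for oxidative phosphorylation, 10 down for BMP targets and 9 down for NF-kB targets. Those of the other lists equalled the counts over all genes.

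**Figure D2:**
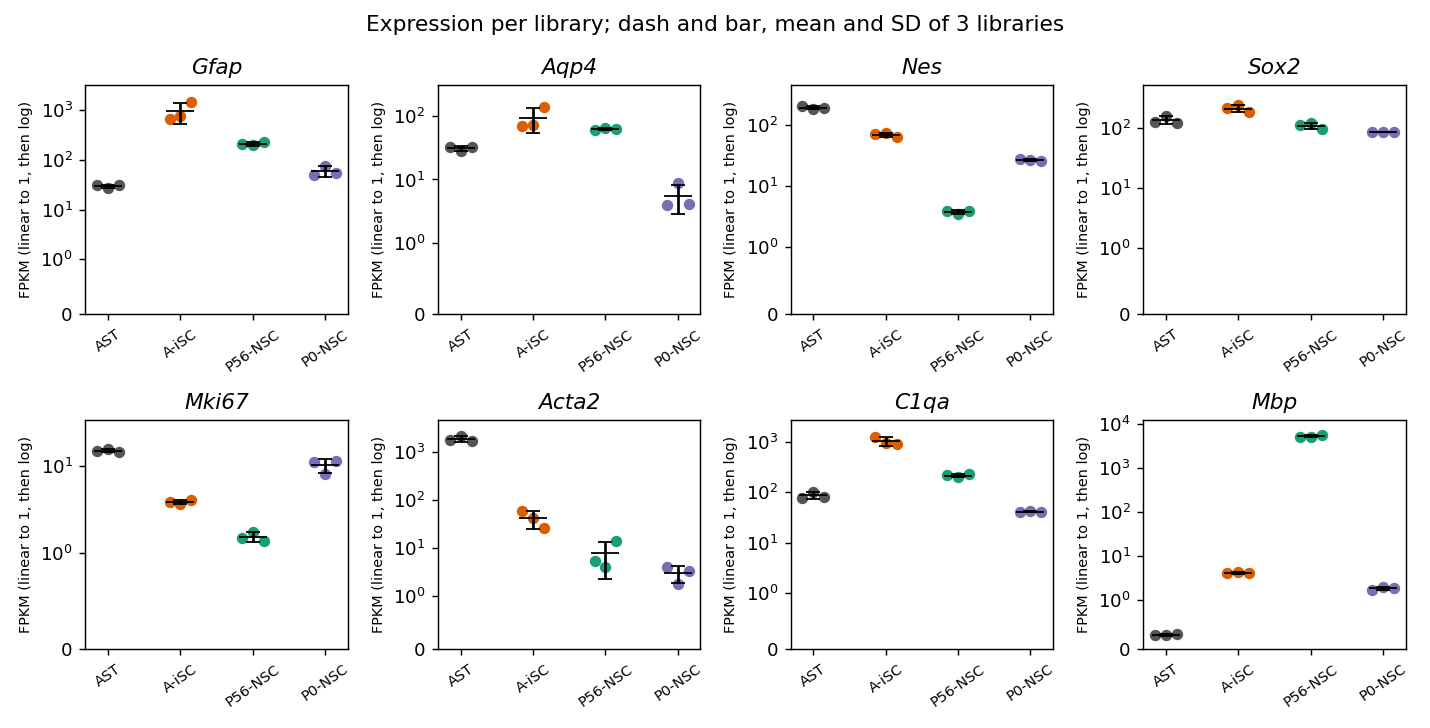
FPKM of 8 genes in each of the 12 libraries (points), with the mean (dash) and SD (bar) of the 3 libraries of each group. The vertical axis is FPKM on a log scale that is linear below 1; Gfap is highest in A-iSC (970.0 ± 448 FPKM), Acta2 in AST (1848 ± 231) and Mbp in P56-NSC (5271 ± 347).

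AST 2, A-iSC 1 and A-iSC 2 had higher levels of short genes than the other libraries of their groups. The Spearman correlations across genes of their deviation from the group mean with gene length were -0.538, -0.335 and -0.268, against 0.458 in AST 1, 0.483 in AST 3 and 0.359 in A-iSC 3. With only the first 3 of these and the 6 NSC libraries in the fit 8590 genes were called, 2929 of them at 2-fold or more, and with the other 3 and the NSC libraries 8458 and 2708. Each of these fits has 1 library of AST or of A-iSC, which is assumed to vary like the other groups, so the spread comes mostly from the NSC libraries. The call of the mesenchymal transcription factors ended on each side (camera adjusted p = 0.0618 and 0.055), and the Notch list was called on each (0.0402 and 0.04). With AST 1, AST 3 and the lone A-iSC 3, stem and progenitor markers (camera adjusted p = 0.0422) and immediate early genes (0.0367) were called too, under that assumption. Without AST 2 and A-iSC 3, the libraries that stood apart within their groups, 9929 genes were called, 3088 of them at 2-fold or more. These settings were chosen after the data were seen. Of the genes called, 47.7% were higher in A-iSC, and 61.1% when scaled by total reads (48.8% and 61.9% at 2-fold or more).

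The comparison of P56-NSC with AST set the first of the positive controls against the starting cells. Myelin genes, astrocyte markers and red blood cell genes were far higher in P56-NSC, and most genes of matrix, contraction and cell division were lower. The astrocyte, red blood cell, matrix and mitosis lists lost their calls with an estimated correlation (adjusted p = 0.123, 0.256, 0.165 and 0.122). Mbp, the myelin basic protein gene (ENSMUSG00000041607, chromosome 18: 82475146 to 82585637), was at 0.295 ± 0.0153 FPKM in AST and 5271 ± 347 FPKM in P56-NSC (n = 3 per group; log2 change 11.99 ± 0.08, limma adjusted p = 1.8e-16). Kif5a, a kinesin of neurons, rose to 1386 ± 231 FPKM. Mobp, a myelin gene listed at 0 in all 3 AST libraries, was at 2506 ± 172 FPKM. The largest falls were those of Thbs1, to 0.476 ± 0.142 FPKM (log2 change -8.93 ± 0.15, limma adjusted p = 5.08e-13), Timp1, the matrix glycoprotein Tnc and Acta2. Of the genes tested 11665 were called, 5846 higher and 5819 lower in P56-NSC, and 5900 at 2-fold or more (3201 higher, 2699 lower). The share of called genes that were higher was 50.1%, and 38.1% when scaled by total reads (54.3% and 40.2% at 2-fold or more).

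All 22 astrocyte markers were higher in P56-NSC (camera adjusted p = 2.87e-09, and adjusted p = 0.123 with an estimated correlation). The glutamate transporter Slc1a2 was at 1.72 ± 0.131 and 519 ± 28.5 FPKM, S100b at 3.11 ± 0.469 and 479.7 ± 12.3 FPKM and Gfap at 29.9 ± 2.30 and 211 ± 15.4 FPKM. Aqp4 was higher by 0.98 ± 0.28 on the log2 scale (limma adjusted p = 0.00663), a call that ended in 1 of 24 alternatives, scaling by total reads (adjusted p = 4.53e-05 to 0.0547). All 17 oligodendrocyte lineage markers were higher (camera adjusted p = 7.75e-11), with Olig2 going from 26.7 ± 0.915 to 78.8 ± 3.38 FPKM. So were 18 of 22 neuronal markers, with 1 lower (camera adjusted p = 4.34e-06), and 17 of 19 ependymal and cilia genes, with 0 lower (camera adjusted p = 2.78e-06). These 2 lists gave adjusted p = 0.229 and 0.18 with an estimated correlation. Snap25, a synaptic protein gene, rose from 0.0912 ± 0.0308 to 33.7 ± 2.99 FPKM, Tubb3 from 40.7 ± 9.21 to 76.8 ± 7.64 FPKM and the ependymal gene Tmem212 from 0.0251 ± 0.0434 to 96.4 ± 15.9 FPKM. Microglia markers were higher in 14 of 20 cases and lower in 3 (camera adjusted p = 0.00605, and adjusted p = 0.411 with an estimated correlation). The microglial receptor P2ry12 rose to 60.2 ± 0.161 FPKM, and the lysozyme gene Lyz2 fell by 3.80 ± 0.30 on the log2 scale. All 5 red blood cell genes were higher (camera adjusted p = 0.000952, and adjusted p = 0.256 with an estimated correlation), with Hba-a1 at 275 ± 69.0 FPKM against 0.0202 ± 0.0351 in AST.

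Neural stem and progenitor markers were higher in 8 of 22 cases and lower in 9 (camera adjusted p = 0.586). Hes5 rose from 0.463 ± 0.199 to 19.8 ± 4.39 FPKM, and Nes dropped from 196 ± 13.4 to 3.76 ± 0.246 FPKM (log2 change -5.37 ± 0.09, limma adjusted p = 4.66e-13). Sox2 was at 135 ± 20.2 and 107 ± 12.7 FPKM (limma adjusted p = 0.0462), a call that ended in 12 of 24 alternatives (adjusted p = 0.000482 to 0.221), among them without AST 1, AST 2, A-iSC 1, P56-NSC 1, P56-NSC 3 or any P0-NSC library (0.053 to 0.183). Pax6 was at 3.59 ± 0.129 and 2.76 ± 0.154 FPKM (limma adjusted p = 0.0133), a call that ended in 1 of 23 alternatives, without P56-NSC 1 (adjusted p = 0.000266 to 0.0546). All 27 mitosis genes were lower (camera adjusted p = 2.26e-11, and adjusted p = 0.122 with an estimated correlation). Also lower were 31 of 32 DNA replication genes (camera adjusted p = 2.56e-10), all 25 actin and SRF targets (3.44e-10) and 18 of 21 YAP and TEAD targets, with 1 higher (3.37e-06). The same held for 19 of 20 p53 targets, with 1 higher (camera adjusted p = 2.28e-08), 11 of 14 BMP targets, with 1 higher (0.000719), and 10 of 12 mesenchymal transcription factors, with 2 higher (0.000935). Mki67 was at 1.53 ± 0.198 FPKM, Cd44 at 0.534 ± 0.126 FPKM and the BMP target Id1 at 14.0 ± 0.440 FPKM, against 15.1 ± 0.562, 105 ± 2.73 and 336 ± 83.4 FPKM in AST.

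Extracellular matrix genes were lower in 30 of 38 cases and higher in 3 (camera adjusted p = 4.01e-09), interferon-stimulated genes in 23 of 28 and 1 (8.03e-06) and reactive astrocyte genes in 22 of 33 and 5 (0.00013). They gave adjusted p = 0.165, 0.314 and 0.121 with an estimated correlation. The interferon-stimulated gene Isg15 dropped from 166 ± 54.6 to 3.26 ± 2.73 FPKM. Fibroblast and mural markers were lower in 13 of 18 cases and higher in 5 (camera adjusted p = 0.00533), and integrins and cadherins in 16 of 21 and 4 (0.00189). ER stress genes were lower in 16 of 23 cases and higher in 4 (camera adjusted p = 0.00712), and NF-kB targets in 17 of 23 and 5 (0.0103, and 0.0529 when scaled by total reads). These 4 lists gave adjusted p = 0.256, 0.325, 0.165 and 0.325 with an estimated correlation. Oxidative phosphorylation genes were not called as a list (6 of 39 higher, 11 lower; camera adjusted p = 0.51). The mitochondrial genome took 16.5% to 17.6% of reads in P56-NSC against 2.94% to 7.03% in the other 9 libraries. Adjusted over the list alone, 23 reactive genes, 32 replication genes, 10 oxidative phosphorylation genes, 4 Notch genes (against 3) and 0 sex-linked genes (against 1) were lower. The other counts equalled those over all genes.

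The comparison of P0-NSC with AST set the second positive control against the starting cells. Most neuronal, endothelial and ciliary genes were higher in P0-NSC, and most genes of contraction, matrix and the interferon response were lower. None of these lists kept its call with an estimated correlation (adjusted p = 0.0539 to 0.372). Islr2, a neuronal membrane protein gene (ENSMUSG00000051243, chromosome 9: 58196297 to 58204319), rose from 0.288 ± 0.0393 to 226 ± 24.0 FPKM (n = 3 per group; log2 change 7.45 ± 0.12, limma adjusted p = 1.6e-12). Dcx rose from 0.0833 ± 0.0245 to 88.1 ± 6.73 FPKM, the neuronal adhesion gene Cntn2 to 92.1 ± 10.2 FPKM and Tubb3 from 40.7 ± 9.21 to 634 ± 84.2 FPKM. Ttr, the transthyretin gene of the choroid plexus, had the largest rise (log2 change 9.01 ± 0.48, limma adjusted p = 8.22e-09), with 3747, 725.4 and 2265 FPKM in the 3 libraries. Among the largest falls were those of Acta2, to 3.04 ± 1.15 FPKM (log2 change -8.88 ± 0.39, limma adjusted p = 1.73e-09), Thbs1 and Timp1. Of the genes tested 11687 were called, 5658 higher and 6029 lower in P0-NSC, and 5656 at 2-fold or more (2899 higher, 2757 lower). Higher genes made up 48.4% of the called genes, and 59.0% when scaled by total reads (51.3% and 64.1% at 2-fold or more).

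Neuronal markers were higher in 20 of 22 cases with 0 lower (camera adjusted p = 3.31e-09), and endothelial markers in 12 of 13 with 0 lower (2.96e-05). Ependymal and cilia genes were higher in 18 of 19 cases with 1 lower (camera adjusted p = 4.81e-05), and so were all 5 red blood cell genes (0.000777). With an estimated correlation the neuronal list gave adjusted p = 0.18 and the other 3 lists adjusted p = 0.229. Cldn5, a tight junction gene of endothelium, was listed at 0 in all AST libraries and was at 50.8 ± 2.24 FPKM in P0-NSC. Notch pathway genes were higher in 14 of 20 cases and lower in 3 (camera adjusted p = 0.00261), and forebrain patterning genes in 13 of 16 and 2 (0.00565). They gave adjusted p = 0.229 and 0.322 with an estimated correlation. The cortical factor Emx1 went from 0.244 ± 0.0512 to 33.1 ± 4.21 FPKM.

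Neural stem and progenitor markers were higher in 13 of 22 cases and lower in 5 (camera adjusted p = 0.102, and 0.0368 under quantile normalization). Sox11, a factor of immature neurons, rose from 6.40 ± 0.281 to 87.7 ± 15.9 FPKM and Pax6 by 0.30 ± 0.09 on the log2 scale (limma adjusted p = 0.0116, and 0.000248 to 0.0554 over 23 alternatives, the highest under quantile normalization). Nes dropped from 196 ± 13.4 to 26.9 ± 0.914 FPKM. Sox2 went from 135 ± 20.2 to 84.5 ± 0.268 FPKM (limma adjusted p = 0.000809, and 0.000179 to 0.868 over 24 alternatives), with the direction reversed under quantile normalization (0.868). Astrocyte markers were higher in 10 of 22 cases and lower in 10 (camera adjusted p = 0.574). Gfap was at 29.9 ± 2.30 and 60.6 ± 14.5 FPKM and S100b at 3.11 ± 0.469 and 1.11 ± 0.350 FPKM, and Aqp4 fell by 2.34 ± 0.28 on the log2 scale.

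All 25 actin and SRF targets were lower (camera adjusted p = 3.31e-09, and adjusted p = 0.0539 with an estimated correlation), as were 17 of 21 YAP and TEAD targets, with 3 higher (camera adjusted p = 1.9e-05). Mitosis genes were lower in 27 of 27 cases (camera adjusted p = 3.59e-07) and DNA replication genes in 21 of 32, with 2 higher (0.00315), both with adjusted p = 0.229 with an estimated correlation. Mki67 fell by 0.52 ± 0.12 on the log2 scale (limma adjusted p = 0.00156, and 0.000639 to 0.0597 over 24 alternatives, the highest when scaled by total reads). Interferon-stimulated genes were lower in 25 of 28 cases and higher in 1 (camera adjusted p = 3.76e-07), p53 targets in 17 of 20 and 1 (8.45e-07) and NF-kB targets in 20 of 23 and 1 (8.51e-05). Reactive astrocyte genes were lower in 24 of 33 cases and higher in 4 (camera adjusted p = 5e-05). These 4 lists gave adjusted p = 0.229, 0.0539, 0.229 and 0.128 with an estimated correlation. Beside them, microglia markers were lower in 13 of 20 cases and higher in 3 (camera adjusted p = 0.0917). The antiviral gene Ifit3 fell by 5.28 ± 0.17 on the log2 scale to 1.10 ± 0.290 FPKM. Csf1 dropped from 275 ± 2.11 to 4.13 ± 0.388 FPKM and Cd44 from 105 ± 2.73 to 1.07 ± 0.209 FPKM.

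Also lower were 36 of 39 oxidative phosphorylation genes (camera adjusted p = 1.9e-05), 13 of 17 glycolysis genes, with 3 higher (0.00919), and 14 of 22 cholesterol synthesis genes, with 2 higher (0.00596). These 3 calls ended under quantile normalization (camera adjusted p = 0.0798, 0.077 and 0.0798) and with an estimated correlation (adjusted p = 0.292, 0.229 and 0.254 with an estimated correlation). The sterol enzyme gene Msmo1 dropped from 41.8 ± 3.35 to 5.53 ± 0.169 FPKM. Extracellular matrix genes were lower in 24 of 38 cases and higher in 8 (camera adjusted p = 0.00332), integrins and cadherins in 12 of 21 and 4 (0.0128) and BMP targets in 11 of 14 and 2 (0.00436). ER stress genes were lower in 18 of 23 cases and higher in 3 (camera adjusted p = 0.000548), and immediate early genes in 13 of 17 and 1 (0.000564). These 5 lists gave adjusted p = 0.372, 0.37, 0.128, 0.128 and 0.267 with an estimated correlation. Adjusted over the list alone, 25 matrix genes were lower, and 3 BMP targets (against 2) and 1 cholesterol gene (against 2) were higher. The remaining counts equalled those over all genes.

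**Figure D3:**
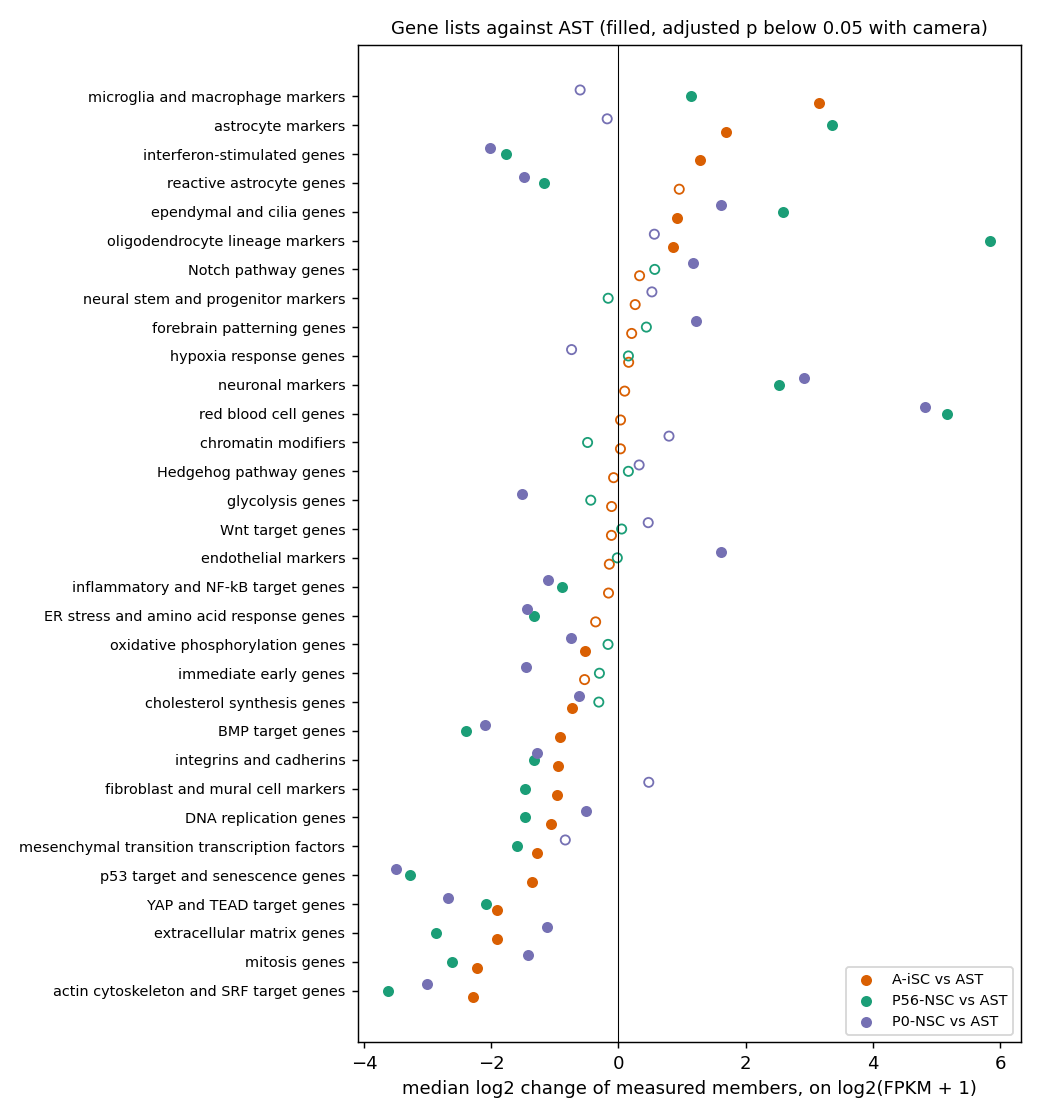
Median log2 change against AST (horizontal axis, log2(FPKM + 1) scale) of the 32 gene lists tested, for A-iSC, P56-NSC and P0-NSC (3 libraries per group), with filled symbols where camera's adjusted p was below 0.05. The lists called numbered 17 for A-iSC, 20 for P56-NSC and 22 for P0-NSC.

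A-iSC was then set against each positive control directly. Against P56-NSC, most genes of the interferon response, of macrophages and of matrix were higher in A-iSC, and most genes of myelin, neurons and astrocytes were lower. None of these lists kept its call with an estimated correlation (adjusted p = 0.0559 to 0.317). Spp1, the osteopontin gene (ENSMUSG00000029304, chromosome 5: 104435118 to 104441050), was at 1.34 ± 0.406 FPKM in P56-NSC and 1523 ± 305 FPKM in A-iSC (n = 3 per group; log2 change 9.34 ± 0.18, limma adjusted p = 2.8e-12). It was followed by Lyz2 (log2 change 6.99 ± 0.30), the macrophage glycoprotein gene Gpnmb (0.701 ± 0.159 and 155 ± 29.9 FPKM) and Ripply1. Mobp (log2 change -11.23 ± 0.07, limma adjusted p = 3.85e-16), Ttr and Mbp were among the lowest relative to P56-NSC, with Mbp at 4.23 ± 0.195 FPKM in A-iSC. Of the genes tested 9897 were called, 4961 higher and 4936 lower in A-iSC, and 3851 at 2-fold or more (1442 higher, 2409 lower). The higher share was 50.1%, and 74.1% when scaled by total reads (37.4% and 66.1% at 2-fold or more).

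Nes was at 3.76 ± 0.246 in P56-NSC and 70.1 ± 5.01 FPKM in A-iSC (log2 change 3.90 ± 0.09, limma adjusted p = 8.58e-12), Sox2 at 107 ± 12.7 and 208 ± 26.9 FPKM and Pax6 at 2.76 ± 0.154 and 4.13 ± 0.533 FPKM. Of 22 neural stem and progenitor markers 9 were higher and 3 lower (camera adjusted p = 0.0359, and adjusted p = 0.3 with an estimated correlation), a call that ended under quantile normalization (camera adjusted p = 0.0594) and without P56-NSC 1, P56-NSC 3 or A-iSC 3 (0.0551, 0.0732 and 0.0847). Astrocyte markers were lower in 18 of 22 cases and higher in 3 (camera adjusted p = 5.51e-05, and adjusted p = 0.276 with an estimated correlation). S100b was at 479.7 ± 12.3 and 11.4 ± 0.992 FPKM, while Gfap was higher in A-iSC (211 ± 15.4 and 970.0 ± 448 FPKM). Aqp4 was at 61.8 ± 2.13 and 92.4 ± 38.5 FPKM (limma adjusted p = 0.135, and 0.00515 to 0.506 over 24 alternatives, called in 2). All 17 oligodendrocyte lineage markers were lower (camera adjusted p = 1.21e-12), as were 18 of 22 neuronal markers (8.8e-08), 17 of 19 ependymal and cilia genes, with 1 higher (2.31e-05), and all 5 red blood cell genes (0.000181). These 4 lists gave adjusted p = 0.0559, 0.192, 0.228 and 0.228 with an estimated correlation. Olig2 was at 78.8 ± 3.38 and 35.9 ± 3.05 FPKM and Tubb3 at 76.8 ± 7.64 and 37.8 ± 9.68 FPKM.

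Interferon-stimulated genes were higher in A-iSC in 27 of 28 cases (camera adjusted p = 1.87e-12, and adjusted p = 0.192 with an estimated correlation). Reactive astrocyte genes were higher in 30 of 33 cases and lower in 2 (camera adjusted p = 5.7e-12), and p53 targets in 17 of 20 and 0 (4.49e-07). Isg15 was at 3.26 ± 2.73 and 174 ± 51.3 FPKM and Cd44 at 0.534 ± 0.126 and 31.3 ± 3.14 FPKM. Beside them, microglia and macrophage markers were higher in 15 of 20 cases and lower in 2 (camera adjusted p = 0.00017, and adjusted p = 0.276 with an estimated correlation). Mitosis genes were higher in 21 of 27 cases and lower in 1 (camera adjusted p = 0.000806), and replication genes in 22 of 32 and 0 (0.000294), with Mki67 at 1.53 ± 0.198 and 3.90 ± 0.205 FPKM. Matrix genes were higher in 25 of 38 cases and lower in 7 (camera adjusted p = 0.000181), and actin and SRF targets in 16 of 25 and 2 (0.000545). These 4 lists gave adjusted p = 0.347, 0.192, 0.317 and 0.192 with an estimated correlation. The fibronectin gene Fn1 was higher by 5.52 ± 0.18 on the log2 scale. ER stress genes were higher in 17 of 23 cases and lower in 4 (camera adjusted p = 0.00789), and chromatin modifiers in 14 of 21 and 2 (0.00797). They gave adjusted p = 0.192 and 0.228 with an estimated correlation.

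The calls of 7 lists ended when scaled by total reads. Higher in A-iSC among these were hypoxia genes in 15 of 25 cases, with 4 lower (camera adjusted p = 0.045, then 0.118), integrins and cadherins in 11 of 21, with 4 lower (0.0359, then 0.238), and BMP targets in 10 of 14, with 2 lower (0.00581, then 0.0602). These 3 lists gave adjusted p = 0.347, 0.478 and 0.192 with an estimated correlation. NF-kB targets were higher in 17 of 23 cases, with 4 lower (camera adjusted p = 0.00645, then 0.114), and mesenchymal factors in 8 of 12, with 1 lower (0.0353, then 0.219). Oxidative phosphorylation genes were lower in 23 of 39 cases, with 1 higher (camera adjusted p = 0.00125, then 0.161), and cholesterol genes in 14 of 22, with 1 higher (0.0117, then 0.237). The last 4 lists gave adjusted p = 0.3, 0.192, 0.425 and 0.3 with an estimated correlation. The hypoxia and integrin calls also ended under quantile normalization (camera adjusted p = 0.0669 for each), and the hypoxia call without shared members (0.205). Leaving out 1 library ended the calls of hypoxia genes (without A-iSC 2, A-iSC 3 or any NSC library, camera adjusted p = 0.0514 to 0.0941) and of integrins and cadherins (without A-iSC 3 or any P56-NSC library, 0.0511 to 0.124). The same held for NF-kB targets without A-iSC 2 or A-iSC 3 (0.0553 and 0.0606) and for mesenchymal factors without any AST library, P56-NSC 1 or P56-NSC 3 (0.0512 to 0.0677). The mitochondrial genome took 16.5% to 17.6% of P56-NSC reads, which stands beside the oxidative phosphorylation count. Adjusted over the list alone, higher counts were 22 for mitosis, 23 for replication, 26 for matrix and 5 for forebrain genes (against 4). Lower counts were 5 for hypoxia (against 4), 8 for matrix, 4 for Hedgehog (against 3), 1 for interferon (against 0), 2 for mesenchymal (against 1) and 9 for forebrain genes (against 8). All others equalled those over all genes.

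Against P0-NSC, A-iSC had higher levels of interferon, macrophage and astrocyte genes and lower levels of neuronal and vascular genes. No list kept its call with an estimated correlation (adjusted p = 0.119 or more). Lyz2 (ENSMUSG00000069516, chromosome 10: 117277331 to 117282321) was at 14.1 ± 5.57 FPKM in P0-NSC and 2957 ± 632 FPKM in A-iSC (n = 3 per group; log2 change 7.66 ± 0.30, limma adjusted p = 7.92e-10). Serpina3n, Gpnmb and Ifit3 (1.10 ± 0.290 and 196 ± 28.4 FPKM) followed. Lowest relative to P0-NSC were Ttr (log2 change -9.94 ± 0.48, limma adjusted p = 4.94e-09), Hba-a1, Islr2 and the neuronal factor gene Neurod2. The last was at 84.4 ± 11.5 FPKM in P0-NSC and listed at 0 in all A-iSC libraries. Of the genes tested 10597 were called, 5133 higher and 5464 lower in A-iSC, and 4381 at 2-fold or more (2096 higher, 2285 lower).

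Nes was at 26.9 ± 0.914 and 70.1 ± 5.01 FPKM in P0-NSC and A-iSC, Sox2 at 84.5 ± 0.268 and 208 ± 26.9 FPKM and Pax6 at 4.64 ± 0.312 and 4.13 ± 0.533 FPKM (limma adjusted p = 0.196, and 0.0328 to 0.68 over 23 alternatives, the lowest without A-iSC 3). Neural stem and progenitor markers were higher in 8 of 22 cases and lower in 9 (camera adjusted p = 0.96), with the cortical progenitor factor Lhx2 lower by a log2 change of -2.53 ± 0.10. Astrocyte markers were higher in 17 of 22 cases and lower in 2 (camera adjusted p = 3.07e-05, and adjusted p = 0.205 with an estimated correlation). Gfap was at 60.6 ± 14.5 and 970.0 ± 448 FPKM and S100b at 1.11 ± 0.350 and 11.4 ± 0.992 FPKM, and Aqp4 was higher by 3.82 ± 0.28 on the log2 scale. All 28 interferon-stimulated genes were higher (camera adjusted p = 8.99e-14), as were 28 of 33 reactive astrocyte genes, with 4 lower (3.57e-09), and, beside them, 19 of 20 microglia and macrophage markers, with 1 lower (3.57e-09). Neuronal markers were lower in 21 of 22 cases (camera adjusted p = 1.34e-10) and endothelial markers in 13 of 13 (6.48e-07). Each of these 5 lists gave adjusted p = 0.119 with an estimated correlation. Fibroblast and mural markers were lower in 13 of 18 cases and higher in 3 (camera adjusted p = 0.000353, and adjusted p = 0.152 with an estimated correlation). Tubb3 was at 634 ± 84.2 and 37.8 ± 9.68 FPKM, Dcx at 88.1 ± 6.73 and 2.86 ± 0.185 FPKM and Olig2 at 11.6 ± 2.56 and 35.9 ± 3.05 FPKM.

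Mitosis genes were lower in A-iSC in 25 of 27 cases (camera adjusted p = 9.31e-06) and replication genes in 25 of 32, with 2 higher (7.89e-05), and these gave adjusted p = 0.206 and 0.119 with an estimated correlation. Mki67 was at 10.3 ± 1.84 and 3.90 ± 0.205 FPKM in P0-NSC and A-iSC. Wnt targets were lower in 11 of 15 cases (camera adjusted p = 0.000457), Notch genes in 12 of 20, with 3 higher (0.0112), and chromatin modifiers in 15 of 21, with 4 higher (0.0121). The 3 lists gave adjusted p = 0.173, 0.206 and 0.197 with an estimated correlation. All 5 red blood cell genes were lower (camera adjusted p = 0.000353), and so were forebrain patterning genes in 9 of 16 cases, with 3 higher (0.0482), with adjusted p = 0.197 and 0.465 with an estimated correlation. The forebrain call ended under quantile normalization (camera adjusted p = 0.0525), when scaled by total reads (0.0568), without members shared with other lists (0.184) and without AST 1 or AST 3 (0.0501 and 0.0506). The BMP call ended without P0-NSC 2 (camera adjusted p = 0.0563) and that of oligodendrocyte markers without P56-NSC 2, P0-NSC 1 or P0-NSC 3 (0.051, 0.0627 and 0.0574). NF-kB targets were higher in 19 of 23 cases and lower in 1 (camera adjusted p = 9.31e-06), hypoxia genes in 19 of 25 and 1 (1.71e-05), p53 targets in 15 of 20 and 1 (4.17e-05) and glycolysis genes in 14 of 17 and 2 (0.000353). ER stress genes were higher in 16 of 23 cases and lower in 3 (camera adjusted p = 0.00103) and YAP and TEAD targets in 12 of 21 and 4 (0.0284), and each of these last 6 lists gave adjusted p = 0.119 with an estimated correlation. Immediate early genes were higher in 13 of 17 cases and lower in 1 (camera adjusted p = 0.00103), actin and SRF targets in 14 of 25 and 3 (0.00759), BMP targets in 10 of 14 and 2 (0.0367) and oligodendrocyte markers in 10 of 17 and 3 (0.0404). They gave adjusted p = 0.264, 0.206, 0.169 and 0.407 with an estimated correlation. Adjusted over the list alone, higher counts were 29 for reactive, 20 for hypoxia, 20 for NF-kB and 0 for pluripotency genes (against 1). Lower counts were 10 for stem and progenitor, 26 for mitosis, 27 for replication, 13 for Notch and 4 for ER stress genes (against 3), and the rest equalled those over all genes.

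The 2 positive controls also differed from each other. P56-NSC had higher levels of myelin, astrocyte and microglia genes, and P0-NSC of vascular, matrix and cell division genes. No list kept its call with an estimated correlation (adjusted p = 0.116 or more). Mobp, Mbp and the myelin gene Mal were among the genes most raised in P56-NSC, with Mbp at 1.85 ± 0.136 FPKM in P0-NSC and 5271 ± 347 FPKM in P56-NSC (n = 3 per group; log2 change 10.85 ± 0.08, limma adjusted p = 5.27e-16). Neurod1, a neuronal transcription factor gene (log2 change -5.87 ± 0.10, limma adjusted p = 7.37e-13), Tnc, the imprinted RNA gene H19 and Neurod2 led the genes lower in P56-NSC. Of the genes tested 10895 were called, 5553 higher and 5342 lower in P56-NSC, and 4521 at 2-fold or more (2568 higher, 1953 lower). The higher share was 51.0%, and 26.4% when scaled by total reads (56.8% and 25.4% at 2-fold or more).

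All 22 astrocyte markers were higher in P56-NSC (camera adjusted p = 7.37e-11), as were all 17 oligodendrocyte markers (3.79e-12), 17 of 20 microglia markers, with 1 lower (3e-05), and 16 of 19 ependymal genes, with 2 lower (0.0029). These 4 lists gave adjusted p = 0.161, 0.116, 0.262 and 0.405 with an estimated correlation. Gfap was at 60.6 ± 14.5 FPKM in P0-NSC and 211 ± 15.4 in P56-NSC, S100b at 1.11 ± 0.350 and 479.7 ± 12.3 and Olig2 at 11.6 ± 2.56 and 78.8 ± 3.38 FPKM, and Aqp4 was higher by 3.32 ± 0.28 on the log2 scale. Endothelial markers were lower in 12 of 13 cases (camera adjusted p = 4.6e-07), fibroblast and mural markers in 16 of 18, with 1 higher (2.81e-07), and mitosis genes in 26 of 27, with 1 higher (2.58e-08). Replication genes were lower in 29 of 32 cases and higher in 1 (camera adjusted p = 1.37e-08), matrix genes in 31 of 38 and 6 (1.62e-07) and chromatin modifiers in 17 of 21 and 0 (1.02e-05). These 6 lists gave adjusted p = 0.206, 0.116, 0.262, 0.116, 0.262 and 0.116 with an estimated correlation. Mki67 was at 10.3 ± 1.84 and 1.53 ± 0.198 FPKM in P0-NSC and P56-NSC, Tubb3 at 634 ± 84.2 and 76.8 ± 7.64, Nes at 26.9 ± 0.914 and 3.76 ± 0.246 and Pax6 at 4.64 ± 0.312 and 2.76 ± 0.154 FPKM. Cd44 fell by 0.43 ± 0.10 on the log2 scale (limma adjusted p = 0.00258, and 4.25e-05 to 0.106 over 24 alternatives, the highest with a pseudocount of 5). Sox2, at 84.5 ± 0.268 and 107 ± 12.7 FPKM (limma adjusted p = 0.0431), changed direction under quantile normalization (-0.16, adjusted p = 0.168) and when scaled by total reads (-0.29, adjusted p = 0.0571). Its call ended in these and 8 more of 24 alternatives (adjusted p = 0.00417 to 0.168), among them without AST 1, A-iSC 1, P56-NSC 1, P56-NSC 2 or any P0-NSC library (0.0509 to 0.161).

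Neuronal markers as a whole were higher in P56-NSC in 7 of 22 cases and lower in 11 (camera adjusted p = 0.128), with Dcx among the lower genes. Oxidative phosphorylation genes were higher in 31 of 39 cases and lower in 0 (camera adjusted p = 4.25e-05), again beside a mitochondrial share of 16.5% to 17.6% of reads in P56-NSC, and glycolysis genes in 12 of 17 and 1 (0.00987). Wnt targets were lower in 10 of 15 cases and higher in 2 (camera adjusted p = 0.00108). Interferon-stimulated genes were higher in 12 of 28 cases and lower in 0 (camera adjusted p = 0.0236), and NF-kB targets in 12 of 23 and 1 (0.0285). These 5 lists gave adjusted p = 0.405, 0.262, 0.262, 0.573 and 0.405 with an estimated correlation. Stem and progenitor markers were lower in 13 of 22 cases and higher in 6 (camera adjusted p = 0.042, with 0.0688 when scaled by total reads and 0.0671 without shared members). Hypoxia genes were higher in 14 of 25 cases and lower in 3 (camera adjusted p = 0.048, and 0.0596 under quantile normalization). Cholesterol genes were higher in 13 of 22 cases and lower in 2 (camera adjusted p = 0.0479, with 0.104 under quantile normalization and 0.451 when scaled by total reads). These 3 lists gave adjusted p = 0.359, 0.405 and 0.405 with an estimated correlation. Without 1 library the calls ended of interferon genes (without P56-NSC 3 or P0-NSC 2, camera adjusted p = 0.0619 and 0.0683), NF-kB targets (without the same libraries, 0.0637 and 0.0609) and stem markers (without A-iSC 3, P56-NSC 1 or P56-NSC 3, 0.0708, 0.0511 and 0.0674). Those of hypoxia genes ended without any AST, A-iSC or P0-NSC library (0.0507 to 0.0755) and of cholesterol genes without AST 1, AST 3 or any P0-NSC library (0.0501 to 0.078). Adjusted over the list alone, higher counts were 18 for microglia, 1 for actin (against 2) and 11 for NF-kB genes, and the lower count for ER stress genes was 4 (against 5). Otherwise the counts equalled those over all genes.

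Over the 6 comparisons camera called 17, 20, 22, 23, 24 and 18 of the 32 lists tested, in the order given. Calls held with an estimated correlation for DNA replication (adjusted p = 0.0349), YAP and TEAD targets (0.00421), actin and SRF targets (0.0349), p53 targets (0.0349) and mesenchymal factors (0.0388) in A-iSC against AST. In P56-NSC against AST they held for oligodendrocyte markers (adjusted p = 0.0451), DNA replication (0.0374), YAP and TEAD targets (0.0214), actin and SRF targets (0.0374), BMP targets (0.0479), p53 targets (0.0305) and mesenchymal factors (0.0374). They held for YAP and TEAD targets (0.0319) in P0-NSC against AST, for reactive astrocyte genes (0.049) and p53 targets (0.049) in A-iSC against P56-NSC, and for 0 lists in the remaining comparisons, where 12 and 6 lists had an unadjusted camera p under 0.05.

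The median, the mean and camera's direction differed in sign for the glycolysis, Hedgehog and chromatin lists in A-iSC against AST, hypoxia and Wnt in P56-NSC against AST and astrocyte markers in P0-NSC against AST. They also differed for Notch and Hedgehog in A-iSC against P56-NSC, stem and progenitor markers in A-iSC against P0-NSC, and reactive, integrin and Hedgehog lists between the NSC groups. None of these lists was called by camera in those comparisons. Scaling by total reads moved the median change of all genes to 0.12, -0.25, 0.17, 0.44, -0.07 and -0.46 in the 6 comparisons, and quantile normalization to -0.11 in P56-NSC against AST and 0.14 in A-iSC against P56-NSC. Changes are therefore relative to the median gene. No list called by camera changed direction under either scaling.

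The changes that both NSC groups shared were used to ask how far A-iSC changed in the same way. They are not specific to progenitor genes, since stem and progenitor markers were not called as a list in either group against AST (camera adjusted p = 0.586 and 0.102). By limma Nes and all 27 mitosis genes were lower in both groups, and all 5 red blood cell genes were higher. Against AST, 3105 genes were called at 2-fold or more in the same direction in P56-NSC and P0-NSC, 1459 higher and 1646 lower. Of these, 76.1% were also called in that direction in A-iSC (983 higher and 1381 lower), and 4.96% in the opposite one. Unchanged groups simulated against the same AST libraries gave 0.0234% on average and at most 0.190% over 100 draws, and independent lists would give 29.5%. The excess over either value is not a measure of a shared effect, and part of it may come from the AST libraries being shared by all 3 comparisons. These were not split, since with 3 libraries a part would hold 1.

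Across all tested genes (not independent replicates), A-iSC log2 changes against AST correlated at r = 0.622 with those of P56-NSC and 0.518 with P0-NSC. Simulated unchanged groups gave 0.503 and 0.513 on average (at most 0.532 and 0.539) from sharing AST alone, so r cannot be judged against these. The covariances were 0.837 and 0.614, against 0.0153 in the simulations for each, differences of 0.822 and 0.598. The distance to P56-NSC (1 minus the Spearman correlation across genes) was 0.255 ± 0.0190 from A-iSC and 0.357 ± 0.00459 from AST (SD, n = 3, ratio 0.715). The distance to P0-NSC was 0.271 ± 0.0120 and 0.301 ± 0.00629 (ratio 0.901). Both differences gave p = 0.1 in a two-sided exact permutation test, the smallest p that 3 against 3 libraries allow, and the 2 tests form 1 family. A-iSC lay 0.147 ± 0.00425 from AST, and P0-NSC 0.251 ± 0.00740 from P56-NSC.

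**Figure D4:**
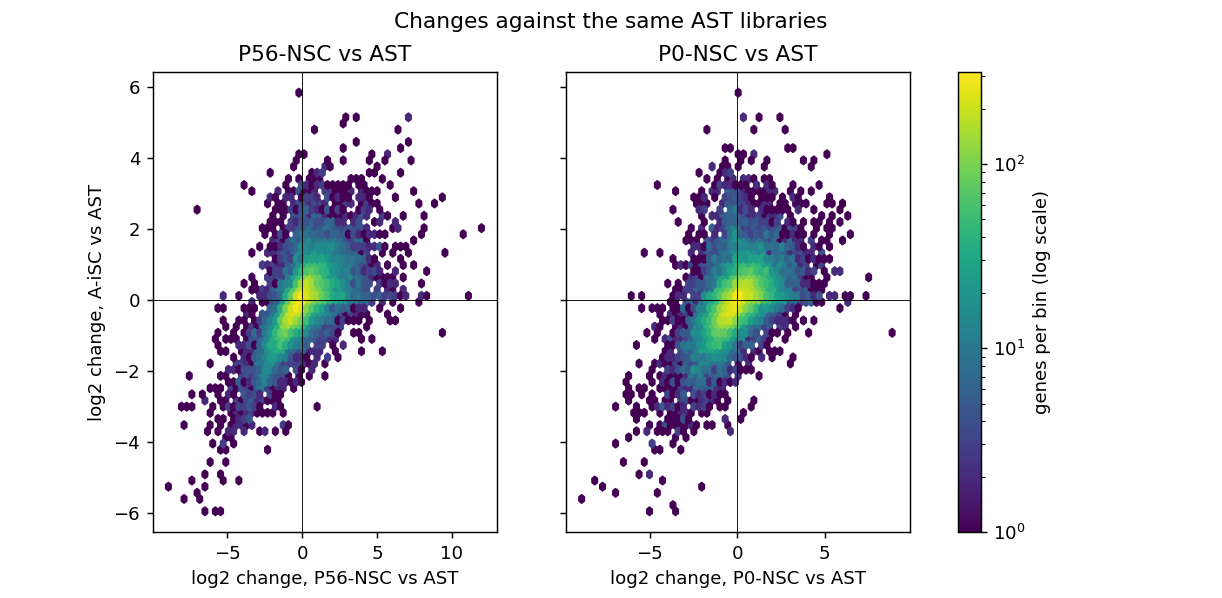
Log2 change of A-iSC against AST (vertical axis) plotted against that of P56-NSC or P0-NSC against AST (horizontal axes), on the log2(FPKM + 1) scale, with shading by the number of genes per hexagon over 15747 genes. Across genes r is 0.622 for P56-NSC and 0.518 for P0-NSC, and the covariance 0.837 and 0.614, against 0.0153 in simulated unchanged groups sharing AST.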

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

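The tests of a lower share of the main cell type, of induction, of the mitochondrial share, of expression by the progenitor cells themselves and of depth, and the counts over other splits of the libraries, were chosen only after the results were seen.

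Loci of the deposited table that carry no gene name stood outside the comparisons, and some of them had signal above the AST controls. Taking a mean of at least 1 FPKM, at least 2-fold the AST mean and above all 3 AST libraries, 43 of the 441 loci were higher in A-iSC, 107 in P56-NSC and 73 in P0-NSC. The highest of the loci above AST in A-iSC lay on the minus strand of chromosome 12 (86693798 to 86695688), at 13.55 ± 2.13 FPKM in A-iSC and 2.45 ± 0.230 FPKM in AST (n = 3 each). The same locus was the highest in P0-NSC, at 50.73 ± 1.28 FPKM. In P56-NSC the highest lay on the plus strand of chromosome 6 (38687512 to 38694379), at 51.47 ± 2.86 FPKM against 7.60 ± 0.383 FPKM in AST. These values were not tested.

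Some genes moved in opposite directions from AST in the positive controls. By limma 86 genes were called at 2-fold or more in both comparisons as higher than AST in P56-NSC and lower than AST in P0-NSC, and 33 the other way (720 and 535 with no fold limit). Calls between P56-NSC and P0-NSC followed for each of the 86 and 33, as this selection nearly requires. Among them, chosen after their values were seen, Plekhb1 was at 22.7 ± 0.938 FPKM in AST, 987.8 ± 73.2 in P56-NSC and 6.58 ± 2.94 in P0-NSC. The cytokine gene Il33 was at 3.43 ± 0.427, 76.5 ± 0.711 and 0.522 ± 0.218 FPKM, and the semaphorin gene Sema3c at 15.98 ± 0.966, 0.585 ± 0.161 and 39.0 ± 2.14 FPKM.

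All 20 microglia and macrophage markers were higher in A-iSC than in AST. A lower share of the main cell type would raise markers of other types alike and lower those of astrocytes. Median log2 FPKM ratios were 3.27 for microglia, 3.21 (3.213) for oligodendrocyte and 3.17 for ependymal genes. Of the latter lists, 4 of 16 and 6 of 19 reached 1 FPKM in AST. Neuronal genes gave 0.67, endothelial -1.14 and fibroblast and mural -1.26, and 17 of 22 astrocyte markers rose. The falls and astrocyte rise argue against this as the whole cause, and a part stays open. A larger share of microglia in A-iSC is a candidate explanation. It predicted that most genes of a second list would rise, and 14 of 15 were called higher. Of the 15, 13 were at 1 FPKM or more in AST and 0 stand in a list fixed at the start. Siglech was not called (0.00588 ± 0.0102 and 0.0391 ± 0.0369 FPKM). Induction in the astrocyte-derived cells stays open, as bulk RNA does not separate the cells. The 20 changes had an SD of 0.888 (range 0.63 to 3.75) with the pseudocount. Without it the quartiles were 2.93 and 3.57, which both explanations allow.

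Myelin transcripts and Ttr were far higher in P56-NSC than in AST. With totals that leave out the mitochondrial genome, the oligodendrocyte list kept a median log2 change of 5.73 (5.734). At 16.5% to 17.6% of P56-NSC reads the mitochondrial share is too small for such changes, so this test allows no conclusion. RNA of other brain cells in the preparation is a candidate explanation, which predicted that most genes of further lists would be higher. Of choroid plexus genes 9 of 10 (90%) were, and of further oligodendrocyte genes 12 of 12. Of these genes 3 and 4 were at 1 FPKM or more in AST and 0 stand in a list fixed at the start. P0-NSC was not tested with these lists, but Ttr and 12 of 13 endothelial markers were higher there too. The labels state no sort or gate. Expression by the progenitor cells stays open, as bulk RNA does not separate the cells, with 8 of 22 stem and progenitor markers higher and 9 lower. All 5 red blood cell genes were higher in both NSC groups. The age or origin of the cells was not tested.

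AST 2, A-iSC 1 and A-iSC 2 deviated from their group mates in a way that followed gene length. Gene length and GC content as the whole of this are argued against, since the within-group differences of AST and A-iSC correlated at r = 0.629 across 10100 genes and still at r = 0.593 after a smooth trend on both was taken out, which held 28.9% and 20.1% of their variance. Depth is argued against too, because the short-gene side had 3.57 × 1e6 more reads in AST and a difference of -4.26 × 1e6 reads in A-iSC. The split as the cause of the difference between A-iSC and AST is argued against by log2 changes that correlated at r = 0.915 between the 2 sides, where 2952 of the 2955 genes called at 2-fold or more kept their sign, although these were picked as called. What the split comes from stays open, and the labels give no batch to test.

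Splitting the 6 libraries of each comparison in other ways gave 10 splits, too few for a share under 0.05, and in each comparison 1 of the 10, the real one, gave as many genes, both with and without the 2-fold limit. For A-iSC against AST limma called 9279 genes (2955 at 2-fold or more) in the real split and at most 831 (94) in another, that of AST 1, AST 3 and A-iSC 3 against the rest, which follows the gene length split (3494 genes at an unadjusted p under 0.05). In the other 5 comparisons the highest other split gave 0 genes with limma, with and without the 2-fold limit, against 11665 (5900), 11687 (5656), 9897 (3851), 10597 (4381) and 10895 (4521) genes in the real one. At an unadjusted p under 0.05 those splits gave at most 258 genes for P56-NSC against AST and 238 for P0-NSC against AST, 1627 and 1218 for A-iSC against P56-NSC and P0-NSC, and 216 between the NSC groups.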

How the results depend on the processing

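The settings chosen only after the results were seen were voom on recovered reads, scaling by total reads, the gene length covariate, the sides of the gene length split and leaving out AST 2 and A-iSC 3.

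Counts of called genes stayed within 1.5 times of those reported in the planned settings and in the added ones that were run. Without 1 library they ranged from 8189 to 9742 for A-iSC against AST, 10420 to 12229 for P56-NSC against AST, 10565 to 12275 for P0-NSC against AST, 8507 to 10565 for A-iSC against P56-NSC, 9301 to 11107 for A-iSC against P0-NSC and 9655 to 11648 between the NSC groups. Counts at 2-fold or more moved further. For A-iSC against AST they rose from 2955 to 4721 with a pseudocount of 0.1, which adds less to low values, and to 4963 with voom. A pseudocount of 5, which shrinks the changes of low values, gave 1269, 2929, 2573, 1851, 1855 and 1944 genes in the 6 comparisons in the order of the text. The gene length covariate gave 10410 genes for A-iSC against AST, 2957 of them at 2-fold or more. The share of the shared NSC genes that moved the same way in A-iSC lay between 65.7% and 82.3% over all settings, the lowest with no fold limit and the highest at 4-fold.

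The ratio of the A-iSC to the AST distance was 0.821 for P56-NSC with no filter and 0.797 with Euclidean distance, against 0.715. For P0-NSC it was 0.856 with voom, and without 1 library it ranged from 0.853 (without A-iSC 1) to 0.949 (without AST 2), against 0.901. Correlations of the fold changes with those of the NSC groups were 0.569 (P56-NSC) and 0.434 (P0-NSC) under quantile normalization and 0.486 (P0-NSC) when scaled by total reads. Gene lists called by camera numbered 5, 7, 1, 2, 0 and 0 in the 6 comparisons with an estimated correlation, and 9, 10, 7, 6, 12 and 6 had an unadjusted p under 0.05. The directional test of fry called 28 lists in A-iSC against AST and 29 between the NSC groups, and its mixed test 31, 32 and 31 in A-iSC against AST, P56-NSC against AST and between the NSC groups, since neither compares a list with other genes. The cause of the other changes was not tested.

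Of 16997 results for single named genes under an alternative, 16856 kept their direction and side of the threshold, 130 lost their call, 7 gained one and 4 reversed. Reversed were Sox2 in P0-NSC against AST (0.019, adjusted p = 0.868) and between the NSC groups (-0.158, adjusted p = 0.168) under quantile normalization, and Sox2 (-0.29, adjusted p = 0.0571) and Uty (-0.011, adjusted p = 0.952) between the NSC groups when scaled by total reads. The range over the alternatives was 0.000179 to 0.868 for Sox2 in P0-NSC against AST, 0.00417 to 0.168 for Sox2 and 0.00683 to 0.952 for Uty between the NSC groups. Of 10290 counts of list members called up or down, 9754 stayed within 1.5 times and 536 moved further. The number of reads limits genes near 1 FPKM most, where a pseudocount moves the fold change.

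The replicate numbers did not pair the libraries, as only 3 of 18 pairs with the same number had deviations correlated above 0.1 (-0.395 to 0.442) and 5 of 12 libraries correlated best with their own number. With the number as a replicate block 9149, 11582, 11633, 9851, 10488 and 10846 genes were called, and 2959, 5898, 5656, 3854, 4382 and 4522 at 2-fold or more. Of the named genes the block moved Myc past the threshold in A-iSC against AST (adjusted p = 0.0521, range over the alternatives 0.00719 to 0.341) and against P0-NSC (0.052, range 0.00378 to 0.221), and no other. Alternatives planned for a table of counts (other size factors, a count test, filters on counts, the choice between counts and normalized values) were left out, because the table gives FPKM, and the reads recovered from it were tested with voom instead.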

Other observations

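No values here come from a planned test, and the genes were chosen after their values were seen.

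Several transcripts of mature brain were most abundant in P56-NSC among the 4 groups. Camk2a, a kinase of excitatory neurons, was at 391 ± 24.5 FPKM in P56-NSC, 6.40 ± 2.49 in P0-NSC, 0.660 ± 0.0158 in A-iSC and 0.805 ± 0.0157 in AST (n = 3 each). Enpp2, a phospholipase gene of the choroid plexus and oligodendrocytes, was at 289.6 ± 59.3 FPKM in P56-NSC, 24.9 ± 4.30 in P0-NSC, 3.36 ± 0.550 in A-iSC and 0.228 ± 0.0538 in AST. Trf, the transferrin gene, was at 452 ± 29.3 FPKM in P56-NSC and 143 ± 15.7 in A-iSC, against 7.71 ± 0.998 in AST and 14.7 ± 0.828 in P0-NSC.

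Transcripts of the mitochondrial ribosomal RNA genes took 3.07% to 3.39% of reads in P56-NSC and 0.0513% to 0.205% in the other 9 libraries. One of them, mt-Rnr1, was at 17198 ± 879.9 FPKM in P56-NSC, 413 ± 125 in P0-NSC, 425 ± 196 in A-iSC and 175 ± 64.7 in AST.

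Gapdh was uneven between libraries of a group, at 41.3, 2.73 and 54.5 FPKM in AST and 53.9, 70.8 and 1.99 FPKM in A-iSC, and it lay at 0.984 to 1.77 FPKM in the 6 NSC libraries. Its many pseudogenes share its sequence, so these values are uncertain.

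Genes of pluripotency and of Hox patterning were mostly under the filter. Of the pluripotency list 16 members stayed under it, with Tbx3 reaching the highest single-library value (1.26 FPKM), and of the hindbrain and Hox list 20 members, none above 0.788 FPKM in any library.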
